A study of Mus musculus with 25 samples.

How the data were processed

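The deposited values of the 25 libraries are log2 values, 1 table per experiment, which the authors made from reads quantified with Salmon against GRCm39, per the labels; software versions are not given in the sources used here. The lowest value in each table is 2, which is log2 of 4, and the values step as log2(n + 4), where n is reads divided by a size factor of the library. Whole reads could be recovered: up to 1000 reads, 100% of values lay within 0.1 of a whole number. The size factors matched median-of-ratios factors, and the tables were normalized separately. The tables list 21106 genes for pups and 19942 for adults; the lowest value of a listed gene's highest library was 0.509 and 0.502 CPM, so low genes had been removed before deposition.

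Values were converted back to normalised counts and tested with limma (3.58.1, with statmod 1.5.0, in R 4.3.3), with trend and robust settings, on log2(value + 1). Genes with a value of at least 1 in as many libraries as the smallest group were kept, which left 21007 and 19857. All groups of an experiment shared a fit, without a replicate term, and p-values were adjusted with Benjamini-Hochberg over all genes tested and called under 0.05. A first look at the data used the deposited offset of 4 before the offset of 1 that had been chosen was fitted; the offset of 4 is among the alternatives. Comparisons, the test, the lists, the gene rule and most alternatives were chosen before the data were examined.

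The 28 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. They cover NRF2 targets (glutathione, detoxification, NADPH), basal, suprabasal and cornified genes, stress keratins, cell cycle, epithelial alarmins, interferon, p53, ATF4 and unfolded protein response, Notch, cholesterol, fatty acids, glycolysis, aryl hydrocarbon receptor targets and immediate early genes. Others mark striated and smooth muscle, fibroblasts, endothelium, leukocytes, nerve and glia, adipose tissue, thyroid and airway, glandular stomach and red blood cells. With an estimated correlation, 4 list calls held over the 9 comparisons together. No cells were classified.

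Named genes were reached by a rule: Nfe2l2, Keap1 and Nqo1 always; called genes with groups that do not overlap and the largest rises and falls, with a mean of at least 2 CPM; and members of called lists with the smallest adjusted p. The planned level, a mean log2 value of 1, was read as a mean of 2. Duplicated symbols were left out. From the genes reached, 196 gene results were chosen for testing under the alternatives after their values were seen. Not all of them are printed, and some left out are results whose call ended without 1 library.

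Effects of a genotype in pups and adults were compared by the difference of log2 fold changes over its standard error, with Welch-Satterthwaite degrees of freedom. That test, thinning to equal depth and the offset of 4 were chosen after seeing the data; a planned joint fit was not run because the tables were normalized separately. Other alternatives were TMM scaling, no filter, limma-voom on recovered reads, offsets of 0.1 and 5, a 2-fold threshold, only the groups compared, striated muscle or Ddx3y as a covariate, a replicate block and leaving out each library. In simulated data with 200 changed genes per comparison, none of them low, the test recovered 75 to 87% of 2-fold and 94 to 100% of 4-fold changes. There, 4 to 13 unchanged genes were called per comparison. Many more genes were called in every real comparison, so false calls there can be more numerous, and recovery of low genes was not simulated. For effect differences it recovered 94 and 93 of 100 planted genes, with 6 and 7 unchanged genes called, and for overlaps 94 and 98 of 100. Coordinates are not used here.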

Results

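Whole-esophagus RNA was sequenced from mice carrying a cancer-derived NRF2 mutation or lacking KEAP1 in squamous cells. NRF2 (gene Nfe2l2) is the transcription factor that activates glutathione and detoxification genes, and KEAP1 is the adaptor that targets NRF2 for degradation. The L30F knock-in replaces leucine with phenylalanine at codon 30, in the DLGex motif. Recombination used Cre under the keratin 5 promoter, which is active in squamous epithelial cells. In the first experiment (pups, 7 to 10 days old, constitutive Cre), wild type, L30F homozygotes and KEAP1-deficient mice gave 3 libraries each. In the second (adults, 6 to 9 weeks old, inducible CreERT2, 1 week after tamoxifen), wild type, L30F heterozygotes, L30F homozygotes and KEAP1-deficient mice gave 4 libraries each. The labels do not say that each library came from a separate animal, so p-values measure the spread between these 25 libraries.

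The 9 pup libraries held 18.8 to 19.7 M reads over the listed genes. In adults the depth differed by genotype: 27.5 to 32.3 M in wild type, 12.8 to 16.9 M in heterozygotes, 10.9 to 11.6 M in homozygotes and 22.5 to 31.3 M in KEAP1-deficient libraries. Values below are normalised read counts, mean ± SD, and each log2 fold change is on the log2(value + 1) scale, which understates the change of low genes. Pup and adult tables were normalized separately, so their levels are not directly comparable. Adjusted p-values are from limma.

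Keap1 (ENSMUSG00000003308) was lower in every KEAP1-deficient library than in every wild-type library of its experiment. In pups the KEAP1-deficient libraries had 725.4, 825.0 and 789.4 normalised counts, the wild-type libraries 1094.1, 1060.2 and 1053.3, and the L30F homozygotes 1103.8, 958.1 and 1423.5. In adults the KEAP1-deficient libraries had 732.4, 811.5, 720.9 and 764.9, and the wild-type libraries 1160.3, 1163.9, 1192.1 and 1076.7. The adult heterozygotes ranged from 1011.3 to 1253.5 and the homozygotes from 1172.3 to 1386.7. Keap1 fell by 0.46 on the log2 scale in KEAP1-deficient pups (SE 0.13, n = 3, adjusted p = 0.012) and by 0.60 in KEAP1-deficient adults (SE 0.07, n = 4, adjusted p = 8e-06). These reads come from all cells of the tissue, and gene-level counts do not separate squamous from other cells. The L30F substitution itself is not visible in gene-level counts.

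**Figure D1:**
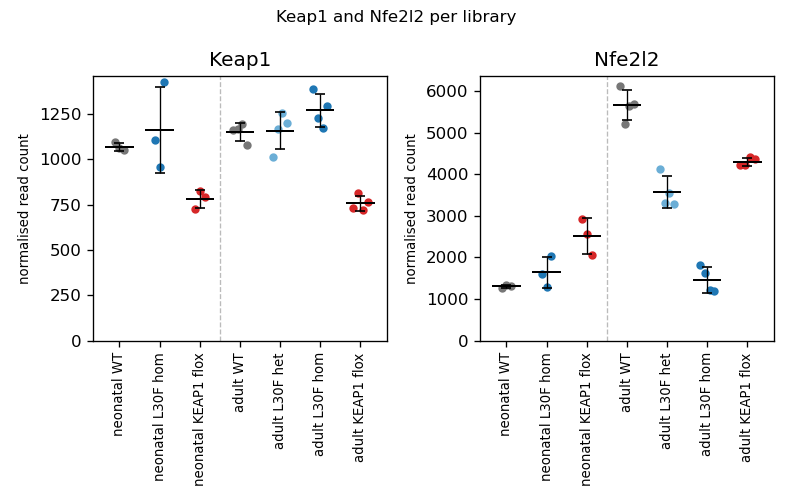
Normalised read counts of Keap1 and Nfe2l2 in each library (points), with group mean (horizontal line) and SD (bar), on linear axes from 0; pups stand left of the dashed line and adults right, and the tables were normalized separately. Adult Nfe2l2 counts lay at 5202.5 to 6110.4 in wild type, 3292.9 to 4117.1 in heterozygotes, 1199.5 to 1806.3 in homozygotes and 4209.5 to 4403.4 in KEAP1-deficient libraries.

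The comparison of L30F homozygous pups with wild type asked what the mutation alone does to the esophagus. The mutant esophagus showed very high expression of NRF2 targets. Slc7a11 (ENSMUSG00000027737), the cystine importer that feeds glutathione synthesis, reached 73520 ± 6330 (SD, n = 3) against 57.7 ± 1.49 in wild type, a log2 fold change of 10.29 (SE 0.07, adjusted p = 1.5e-13). Gclc, the catalytic subunit of glutamate-cysteine ligase, rose 107-fold and Srxn1 57.1-fold. The keratin genes Krt6b and Krt16 rose 98.0-fold and 112-fold, while cell cycle genes and fibroblast genes fell. The test called 8225 of 21007 genes, 4632 higher and 3593 lower.

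Of 13 glutathione and thioredoxin genes, 12 rose (12 adjusted over the list alone) and the other was not called; the median log2 change was 3.93 (camera adjusted p = 7.5e-16, and adjusted p = 0.028 with an estimated correlation). Of 35 detoxification genes, 33 rose, 0 fell and 2 were not called (adjusted over the list alone, 33 rose and 1 fell; camera adjusted p = 2.7e-25, and adjusted p = 0.028 with an estimated correlation). These included Nqo1 (ENSMUSG00000003849), a quinone reductase, at 9989 ± 445 against 76.7 ± 4.42 (log2 fold change 7.01, SE 0.08, adjusted p = 1e-11). They also included the glutathione transferase Gstm1, 134-fold higher (log2 fold change 7.07, SE 0.09, adjusted p = 1.5e-11). All 8 NADPH-producing enzymes of the list rose (8 adjusted over the list alone, camera adjusted p = 3.4e-08, adjusted p = 0.11 with an estimated correlation), among them G6pdx 11.4-fold and Pgd 7.23-fold. Nfe2l2 itself had 1641 ± 371 against 1301 ± 38.2 (log2 fold change 0.31, SE 0.17, adjusted p = 0.17). It was called without homozygote library 2 (0.47, adjusted p = 0.041) and in no other of the 9 leave-one-out fits.

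All 4 stress keratins rose (4 adjusted over the list alone, camera adjusted p = 6.2e-06, adjusted p = 0.11 with an estimated correlation): Krt6b had 76800 ± 4920 against 785.1 ± 95.2 and Krt16 18110 ± 2450 against 159.8 ± 3.68. Of 37 cornified envelope genes, 31 rose, 1 fell and 5 were not called (adjusted over the list alone, 32 rose and 1 fell; camera adjusted p = 1.6e-15, adjusted p = 0.11 with an estimated correlation). Transglutaminase Tgm1, which crosslinks envelope proteins, had 8557 ± 182 against 1520 ± 143 (5.64-fold, adjusted p = 5e-09). Sprr2b rose from 2.34 ± 1.35 to 2861 ± 730 and Lce3d from 2.59 ± 2.94 to 1956 ± 287, both uncertain because these families hold near-identical copies. Of 16 suprabasal genes, 12 rose, 3 fell and 1 was not called (12 and 3 adjusted over the list alone, camera adjusted p = 3e-06, adjusted p = 0.11 with an estimated correlation), with Dmkn 20.7-fold and Sbsn 7.32-fold higher. Basal layer genes split: 5 of 16 rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.92). Among them Krt14 rose 6.74-fold and Trp63 2.61-fold, while Pdpn fell by 1.12 on the log2 scale (SE 0.12, adjusted p = 4.4e-05).

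Of 19 epithelial alarmin and cytokine genes, 12 rose and 7 were not called (adjusted over the list alone, 13 rose and 1 fell; camera adjusted p = 4.2e-06, adjusted p = 0.11 with an estimated correlation). Il1f9, which encodes the epithelial cytokine IL-36 gamma, had 5148 ± 384 against 37.0 ± 14.7 (log2 fold change 7.15, SE 0.21, adjusted p = 1.9e-08), and Il1a rose 8.16-fold. Of 16 cholesterol genes, 15 rose (16 adjusted over the list alone, camera adjusted p = 3.2e-12, adjusted p = 0.11 with an estimated correlation), with Fdft1 4.28-fold higher. Cell cycle genes fell: 18 of 20 (19 adjusted over the list alone, camera adjusted p = 3e-07, adjusted p = 0.28 with an estimated correlation), with Mcm2, part of the replication helicase, at 393.9 ± 62.2 against 811.3 ± 84.0 (log2 fold change -1.05, SE 0.13, adjusted p = 0.00017). Of 12 fibroblast genes, 11 fell (adjusted over the list alone, 11 fell and 1 rose; camera adjusted p = 4.4e-05, adjusted p = 0.27 with an estimated correlation), among them Dcn at 7212 ± 1060 against 15770 ± 1770. Of 20 striated muscle genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone; median -0.24). Smooth muscle genes fell in 3 of 10 cases (1 adjusted over the list alone; median -0.84, camera adjusted p = 0.038, adjusted p = 0.60 with an estimated correlation), and their mean log2 value was 11.369, 12.414 and 10.758 in homozygote libraries 1, 2 and 3 against 12.327 to 12.355 in wild type. Muc4, a membrane mucin, was among the largest falls, from 4896 ± 1180 to 117.3 ± 158.0 (log2 fold change -6.59, SE 1.24, adjusted p = 0.0055). Homozygote library 3 was the only pup library that lacked Ddx3y reads and had high Xist. Without it 7542 genes were called.

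**Figure D2:**
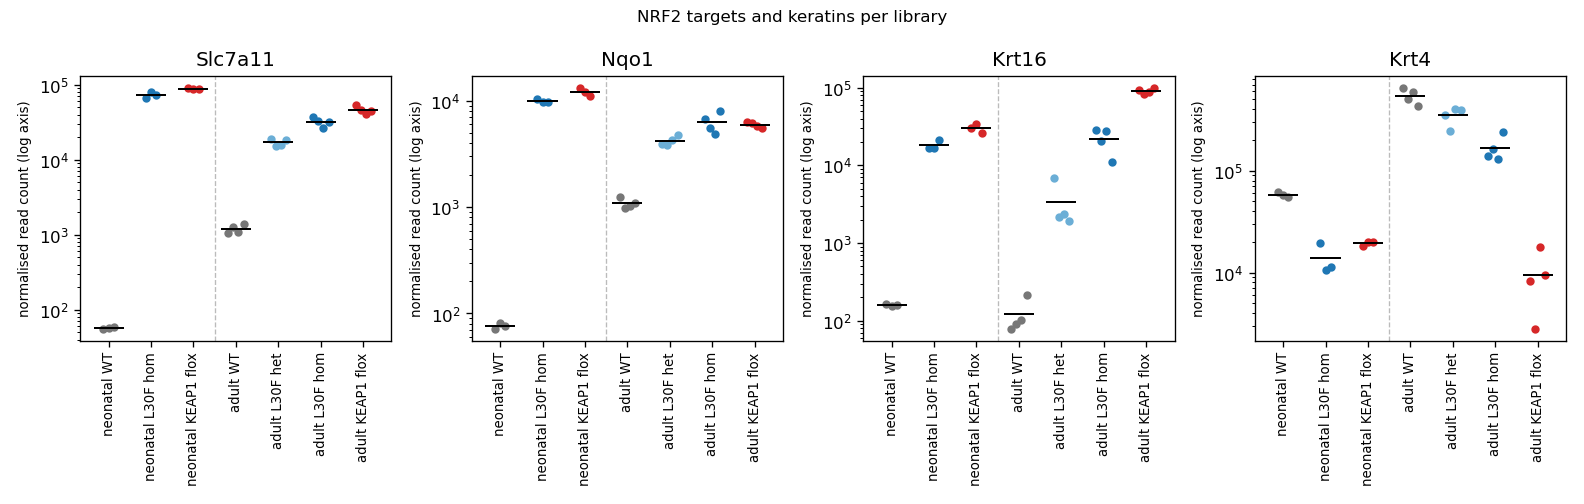
Normalised read counts (log axis) of Slc7a11, Nqo1, Krt16 and Krt4 in each library (points) with the group mean (line); pups stand left of the dashed line and adults right. Mean Krt4 was 544700 in adult wild type, 349800 in heterozygotes, 168800 in homozygotes and 9559 in KEAP1-deficient adults.

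NRF2 targets and stress keratins rose in KEAP1-deficient pups, which were compared with the same wild-type libraries. Slc7a11 had 88720 ± 1840 against 57.7 ± 1.49 (SD, n = 3; log2 fold change 10.56, SE 0.07, adjusted p = 1.2e-13), Nqo1 12120 ± 1050 against 76.7 ± 4.42 (7.28, SE 0.08, adjusted p = 6.9e-12), and Gstm1 rose 134-fold. Krt6b reached 134600 ± 8450 and Krt16 30100 ± 3700, 172-fold and 186-fold above wild type. Nfe2l2 (ENSMUSG00000015839) rose to 2513 ± 440 from 1301 ± 38.2 (0.93, SE 0.17, adjusted p = 0.0013). The test called 10404 genes, 5528 higher and 4876 lower.

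Of 13 glutathione genes 12 rose (13 adjusted over the list alone, camera adjusted p = 4.6e-14, and adjusted p = 0.042 with an estimated correlation). Among 35 detoxification genes 33 rose (34 adjusted over the list alone, camera adjusted p = 1.1e-21, and adjusted p = 0.042 with an estimated correlation). All 8 NADPH enzymes rose (8 adjusted over the list alone, camera adjusted p = 2.9e-07, adjusted p = 0.12 with an estimated correlation), with G6pdx at 11300 ± 519 against 796.8 ± 50.5. All 4 stress keratins rose (4 adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.12 with an estimated correlation). Of 37 cornified envelope genes 33 rose and 1 fell (33 and 1 adjusted over the list alone, camera adjusted p = 1.1e-14, adjusted p = 0.12 with an estimated correlation). Of 16 suprabasal genes 12 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 8.4e-06, adjusted p = 0.12 with an estimated correlation). Tgm1 rose 8.56-fold, Sbsn 12.1-fold and Il1f9 185-fold, to 6700 ± 226 (log2 fold change 7.53, SE 0.21, adjusted p = 1e-08). All 16 cholesterol genes rose (16 adjusted over the list alone, camera adjusted p = 1.1e-11, adjusted p = 0.13 with an estimated correlation). Of 16 basal genes 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.79): Krt14 rose 8.48-fold, and Pdpn fell by 1.14 on the log2 scale (SE 0.12, adjusted p = 2.6e-05).

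Cell cycle genes fell in 14 of 20 cases (14 adjusted over the list alone, camera adjusted p = 0.00038, adjusted p = 0.48 with an estimated correlation), with Cdk1 at 248.5 ± 32.5 against 405.7 ± 15.0 (log2 fold change -0.71, SE 0.12, adjusted p = 0.00069). Of 12 fibroblast genes 11 fell (11 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.23 with an estimated correlation), with Mfap5 at 843.8 ± 151.0 against 2413 ± 131. Red blood cell genes fell in 5 of 7 cases (5 adjusted over the list alone; median -3.12, camera adjusted p = 0.0065, adjusted p = 0.43 with an estimated correlation). Smooth muscle genes fell in 4 of 10 (7 adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.48 with an estimated correlation). The antimicrobial gene Reg3g had 0.711 ± 1.23 against 524.3 ± 236.0 (log2 fold change -8.36, SE 2.64, adjusted p = 0.035), a call that limma-voom did not make (adjusted p = 0.15) and that the muscle covariate ended (-8.40, SE 2.95, adjusted p = 0.062). It also ended when any 1 of the 6 compared libraries was left out. Over those fits adjusted p was 0.079, 0.085 and 0.069 without the wild-type libraries 1, 2 and 3, and 0.069, 0.099 and 0.084 without the KEAP1-deficient libraries 1, 2 and 3.

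The direct comparison of the mutants in pups asked how L30F differs from KEAP1 loss. The test called 875 genes, 370 higher and 505 lower in L30F homozygotes, and the differences in NRF2 targets were small beside those from wild type. Akr1b8, an aldo-keto reductase, had 6284 ± 316 in homozygotes against 10370 ± 628 in KEAP1-deficient pups (SD, n = 3; log2 fold change -0.72, SE 0.08, adjusted p = 0.0088), and Pgd was lower by a similar amount (-0.67, SE 0.09, adjusted p = 0.013). Krt6b had 76800 ± 4920 against 134600 ± 8450 (-0.81, SE 0.09, adjusted p = 0.0088). Nqo1 had 9989 ± 445 against 12120 ± 1050 (-0.28, SE 0.08, adjusted p = 0.077). The fibroblast gene Mfap5 was 2.05-fold higher in homozygotes (adjusted p = 0.0088).

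Among 13 glutathione genes 2 were lower in homozygotes (8 adjusted over the list alone, camera adjusted p = 0.00022, adjusted p = 0.27 with an estimated correlation). Of 35 detoxification genes 5 were lower and 1 higher (15 and 1 adjusted over the list alone, camera adjusted p = 5.7e-06, adjusted p = 0.27 with an estimated correlation). Among 16 suprabasal genes 5 were lower and 1 higher (10 and 1 adjusted over the list alone, camera adjusted p = 1.3e-05, adjusted p = 0.27 with an estimated correlation), Sbsn among them (-0.73, SE 0.09, adjusted p = 0.0088). Of 16 cholesterol genes 4 were lower (15 adjusted over the list alone, camera adjusted p = 7.2e-09, adjusted p = 0.27 with an estimated correlation). Tgm1 was lower (-0.60, SE 0.08, adjusted p = 0.01), 1 of 2 cornified envelope genes of 37 called lower (6 adjusted over the list alone, camera adjusted p = 0.00035, adjusted p = 0.46 with an estimated correlation). Camera called some lists of other cell types up in homozygotes, with few members called. Red blood cell genes were higher in 1 of 7 cases (4 adjusted over the list alone, median 2.91, camera adjusted p = 1.2e-05, adjusted p = 0.27 with an estimated correlation). Fibroblast genes were higher in 1 of 12 (5 adjusted over the list alone, camera adjusted p = 5.2e-05, adjusted p = 0.30 with an estimated correlation). Nerve and glia genes were higher in 1 of 10 (3 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.27 with an estimated correlation). Camera also called endothelial genes up (median 0.23, adjusted p = 0.014, adjusted p = 0.46 with an estimated correlation) and smooth muscle genes up (median 0.46, adjusted p = 0.033, adjusted p = 0.65 with an estimated correlation), each with 0 of 10 members called (0 adjusted over the list alone). Leukocyte and adipose lists were not called (camera adjusted p = 0.37 each). Striated muscle genes were not called either (median -0.25, 2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.069). Nfe2l2 had 1641 ± 371 against 2513 ± 440 (-0.62, SE 0.17, adjusted p = 0.066), and this was called without homozygote library 3 (-0.79, adjusted p = 0.026) and with Ddx3y as a covariate (-0.79, adjusted p = 0.027). In pups that covariate nearly repeats leaving out homozygote library 3, the only pup library without Ddx3y reads. Keap1 was higher in homozygotes (0.56, SE 0.13, adjusted p = 0.042), and leaving out any library but homozygote library 3 ended that call, with adjusted p from 0.053 to 0.1.

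The count of 875 rested on few libraries. It was 120 and 207 without wild-type library 2 or 3, and 172 and 63 without homozygote library 1 or 2. Without KEAP1-deficient library 1, 2 or 3 it was 177, 47 and 392. It was 185 when the fit held only the groups compared and 222 with a replicate block. The balance turned as well: at 2-fold 118 genes were higher and 30 lower in homozygotes, and with Ddx3y as a covariate 450 and 393. That covariate mostly sets homozygote library 3 apart, so it is close to leaving that library out. The share of calls higher in homozygotes, 42.3% in all libraries, was 55.6% and 54.3% without homozygote library 2 or 3, and 54.8%, 53.2% and 50.5% without KEAP1-deficient library 1, 2 or 3.

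Against wild type, 7287 genes were called in the same direction in both pup mutants, 4271 higher and 3016 lower, and 1 gene in opposite directions. Independent lists of the same sizes would share 1219 higher and 834 lower genes, and 50 simulations of unchanged groups with the same controls shared on average 0 and 0.02. Almost no gene is called in unchanged groups, so these counts do not show how shared controls act where many genes change. Across genes, which are not independent replicates, the fold changes correlated at 0.913 (simulated 0.502), with covariance 1.484 (simulated 0.087). The 3 controls could not be split, so the part due to sharing them was not measured with split controls.

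In adult L30F heterozygotes 7 of 13 glutathione genes, 20 of 35 detoxification genes and 3 of 4 stress keratins rose, and 12 of 20 cell cycle genes fell. None of the list calls held with an estimated correlation. Slc7a11 had 17190 ± 1910 against 1210 ± 163 in wild type (SD, n = 4; log2 fold change 3.83, SE 0.12, adjusted p = 1.5e-11), Gclc rose 18.0-fold and Nqo1 3.86-fold. Krt16 had 3351 ± 2390 against 122.0 ± 63.2 (4.67, SE 0.41, adjusted p = 1.2e-05) and Krt6b rose 18.9-fold. The metallothionein gene Mt3 rose 23.2-fold, to 1100 ± 224, and Epgn, which encodes the EGF receptor ligand epigen, 22.8-fold, to 234.1 ± 155.0. The test called 1927 of 19857 genes, 954 higher and 973 lower. Heterozygote and wild-type depths did not overlap (12.8 to 16.9 M reads against 27.5 to 32.3 M).

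Of 13 glutathione genes 7 rose (11 adjusted over the list alone, camera adjusted p = 2.1e-16, adjusted p = 0.073 with an estimated correlation), among them Gclm at 2525 ± 195 against 962.6 ± 49.7. Among 35 detoxification genes 20 rose and 15 were not called (25 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.1e-19, adjusted p = 0.073 with an estimated correlation), among them the exporter Abcc4, 3.97-fold, and Gsta1, 5.50-fold. Of 4 stress keratins 3 rose (3 adjusted over the list alone, camera adjusted p = 3.4e-06, adjusted p = 0.079 with an estimated correlation). Of 8 NADPH enzymes 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.81). Nfe2l2 fell to 3565 ± 385 from 5662 ± 371 (log2 fold change -0.67, SE 0.12, adjusted p = 0.0028), and Keap1 had 1158 ± 104 against 1148 ± 49.8 (adjusted p = 0.96).

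Of 16 suprabasal genes 4 fell (6 adjusted over the list alone, camera adjusted p = 9.4e-05, adjusted p = 0.40 with an estimated correlation), with Calml3 at 6290 ± 1300 against 12400 ± 1160 (SE 0.16 on the log2 scale, adjusted p = 0.0014). Of 37 cornified envelope genes 10 fell (13 fell and 2 rose adjusted over the list alone, camera adjusted p = 0.00059, adjusted p = 0.40 with an estimated correlation), with envoplakin gene Evpl at 14120 ± 2530 against 21600 ± 1890. Sprr3 had 16030 ± 4910 against 33540 ± 7640 (-1.10, SE 0.25, adjusted p = 0.016), with adjusted p = 0.062 without wild-type library 1, 0.052 without wild-type library 3 and 0.052 in a fit of only these groups. Of 20 cell cycle genes 12 fell (14 fell and 3 rose adjusted over the list alone, camera adjusted p = 9.4e-05, adjusted p = 0.36 with an estimated correlation), with Top2a at 749.3 ± 183.0 against 1640 ± 517 (-1.09, SE 0.23, adjusted p = 0.0097). The Top2a call ended in a fit of only these groups (-1.09, SE 0.28, adjusted p = 0.061) and with Ddx3y as a covariate (-0.93, SE 0.26, adjusted p = 0.068). Wild-type library 4 stood apart here, with a mean cell cycle value of 7.767 on the log2 scale against 8.563 to 8.702 in the other wild-type libraries. Other cell types moved as well: 8 of 20 striated muscle genes rose (14 adjusted over the list alone, camera adjusted p = 7.8e-08, adjusted p = 0.32 with an estimated correlation), with Myh1 at 176400 ± 23400 against 106900 ± 11900 (0.72, SE 0.14, adjusted p = 0.0059), a call that ended with Ddx3y as a covariate (0.59, SE 0.16, adjusted p = 0.053). Of 10 nerve and glia genes 2 rose (5 adjusted over the list alone, camera adjusted p = 0.00059, adjusted p = 0.25 with an estimated correlation), with Tubb3 3.80-fold higher, and of 12 fibroblast genes 2 rose (6 adjusted over the list alone, camera adjusted p = 0.00059, adjusted p = 0.43 with an estimated correlation).

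The count of 1927 fell to 623, 1151 and 968 without wild-type library 1, 2 or 3 and was 2448 without library 4. It was 809 in a fit of only these groups and 653 with Ddx3y as a covariate. Ddx3y was higher in every heterozygote library than in every wild-type library, so that covariate moves with genotype here. With the striated muscle mean as a covariate it was 113, 80 higher and 33 lower (70.8% higher, against 49.5% without it), and 11 of 23 gene results were no longer called. Among the 11 are Myh1 and Myoz1, which are part of the muscle mean and were adjusted in part for themselves. Standard errors grew while several folds changed little. Nfe2l2 went from -0.67 (SE 0.12) to -0.75 (SE 0.17, adjusted p = 0.077), Calml3 from -1 (SE 0.16) to -0.95 (SE 0.24, adjusted p = 0.11), Evpl from -0.63 (SE 0.13) to -0.77 (SE 0.19, adjusted p = 0.11) and Tubb3 from 1.92 (SE 0.25) to 1.71 (SE 0.38, adjusted p = 0.069). Top2a also shrank, from -1.09 (SE 0.23) to -0.82 (SE 0.33, adjusted p = 0.35).

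In adult L30F homozygotes the keratin genes Krt6b, Krt16 and Krt6a and the NRF2 targets Slc7a11, Gclc and Nqo1 were above wild type, while Nfe2l2 and Krt4 were below it. Krt6b had 136900 ± 38800 against 630.9 ± 372.0 (SD, n = 4; log2 fold change 7.87, SE 0.38, adjusted p = 6e-09), Krt16 22060 ± 8200 against 122.0 ± 63.2, and Krt6a 97580 ± 17400 against 2120 ± 1550. Slc7a11 rose 26.4-fold, to 31940 ± 4290 (4.72, SE 0.12, adjusted p = 5.5e-13), Gclc 32.4-fold and Nqo1 5.70-fold. Nfe2l2 fell to 1457 ± 304 from 5662 ± 371 (-1.98, SE 0.12, adjusted p = 1.2e-08). Krt4, the main suprabasal keratin of the esophagus, fell to 168800 ± 49100 from 544700 ± 94200 (-1.72, SE 0.40, adjusted p = 0.0073). The test called 4420 genes, 2348 higher and 2072 lower.

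Among 13 glutathione genes 11 rose (13 adjusted over the list alone, camera adjusted p = 3.1e-18, adjusted p = 0.057 with an estimated correlation), with peroxiredoxin gene Prdx1 4.98-fold higher. Of 35 detoxification genes 24 rose and 2 fell (24 and 3 adjusted over the list alone, camera adjusted p = 5.1e-18, adjusted p = 0.057 with an estimated correlation): Abcc4 rose 6.85-fold, Gsta1 13.4-fold and Akr1c18 66.8-fold, to 436.4 ± 161.0. Of 8 NADPH enzymes 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.25). Of 4 stress keratins 3 rose (4 adjusted over the list alone, camera adjusted p = 2.9e-07, adjusted p = 0.057 with an estimated correlation). Among 16 suprabasal genes 9 fell (10 adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.46 with an estimated correlation), with Calml3 at 3431 ± 539 against 12400 ± 1160. The cornified envelope list split, 7 of 37 higher and 16 lower (7 and 18 adjusted over the list alone, camera adjusted p = 0.093); its median was -0.57 and its mean 0.32, so they differ in sign, and the test's direction was down. Of 16 basal genes 4 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.29): Krt14 rose 4.01-fold and Krt15 fell by 1.38 on the log2 scale (SE 0.25, adjusted p = 0.0018).

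Of 20 cell cycle genes 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0013, adjusted p = 0.46 with an estimated correlation), with Mcm5 at 650.4 ± 111.0 against 312.2 ± 34.1 (log2 fold change 1.05, SE 0.16, adjusted p = 0.00033). Of 21 alarmin and cytokine genes 6 rose (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0044, adjusted p = 0.38 with an estimated correlation), with S100a9 at 6880 ± 8200 against 205.0 ± 89.3 (4.26, SE 0.74, adjusted p = 0.0016). Of 16 interferon-stimulated genes 5 rose (10 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.46 with an estimated correlation), Bst2 1.92-fold. Leukocyte markers rose in 11 of 19 cases (11 adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.46 with an estimated correlation), with Cd68 at 483.3 ± 92.5 against 263.0 ± 55.6. Of 12 fibroblast genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.51 with an estimated correlation), with Col3a1 1.97-fold higher, and of 10 endothelial genes 4 rose (5 adjusted over the list alone, camera adjusted p = 0.0079, adjusted p = 0.51 with an estimated correlation), with Pecam1 1.56-fold higher. Striated muscle genes had a median of 0.01, with 1 of 20 higher and 1 lower (1 and 0 adjusted over the list alone). Depth separated these groups completely, 10.9 to 11.6 M reads against 27.5 to 32.3 M.

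The comparison of KEAP1-deficient adults with wild type asked what KEAP1 loss does in the adult esophagus: keratins of esophageal differentiation fell, and stress keratins and inflammatory genes rose. Krt4 fell to 9559 ± 6120 from 544700 ± 94200 (SD, n = 4; log2 fold change -6.09, SE 0.40, adjusted p = 2.5e-08), Krt13, its partner keratin, to 100400 ± 16200 from 468700 ± 59300 (-2.23, SE 0.14, adjusted p = 7.7e-09), and the basal keratin Krt15 to 317.6 ± 174.0 from 14310 ± 1890 (-5.61, SE 0.25, adjusted p = 6.8e-10). Krt16 rose 800-fold, to 90860 ± 6860, and Krt6b 363-fold, to 205500 ± 12900. S100a8, an antimicrobial alarmin, had 26190 ± 1890 against 53.9 ± 35.5 (9.16, SE 1.05, adjusted p = 1.1e-05). Slc7a11 had 46400 ± 5470 against 1210 ± 163 (5.26, SE 0.12, adjusted p = 1e-13). The test called 9290 genes, 4781 higher and 4509 lower.

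Of 13 glutathione genes 12 rose (13 adjusted over the list alone, camera adjusted p = 5.7e-11, adjusted p = 0.14 with an estimated correlation), Gclc 34.1-fold. Among 35 detoxification genes 23 rose and 5 fell (23 and 6 adjusted over the list alone, camera adjusted p = 3.2e-07, adjusted p = 0.31 with an estimated correlation): Nqo1 rose 5.48-fold and Akr1c18 249-fold, to 1568 ± 307. Of 8 NADPH enzymes 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.097). All 4 stress keratins rose (4 adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.14 with an estimated correlation). Of 16 suprabasal genes 11 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.39 with an estimated correlation), with Calml3 at 1501 ± 242 against 12400 ± 1160 and Krt78 at 2334 ± 956 against 23590 ± 5340. Of 37 cornified envelope genes 20 fell and 11 rose (20 and 12 adjusted over the list alone, camera adjusted p = 0.062); the median was -1.25 and the mean 0.44, of opposite sign, and the test's direction was down. Sprr2f and Sprr2e, of a family with near copies, were among the largest rises, to 7773 ± 2730 from 8.70 ± 3.88 and to 4149 ± 1290 from 2.46 ± 1.87. Of 16 basal genes 7 rose and 5 fell (9 and 5 adjusted over the list alone; median 0.45, camera adjusted p = 0.51, with fry's direction down), and Dst, which anchors hemidesmosomes, fell by 1.11 on the log2 scale (SE 0.08, adjusted p = 1.8e-08).

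Of 21 alarmin and cytokine genes 17 rose and 1 fell (18 and 2 adjusted over the list alone, camera adjusted p = 3e-07, adjusted p = 0.14 with an estimated correlation), with Il1b at 1277 ± 742 against 19.4 ± 22.6 (log2 fold change 6.32, SE 0.60, adjusted p = 8e-07). Of 16 interferon-stimulated genes 14 rose (14 adjusted over the list alone, camera adjusted p = 2.5e-07, adjusted p = 0.31 with an estimated correlation), with Irf7 6.37-fold higher. Of 20 cell cycle genes 15 rose (15 adjusted over the list alone, camera adjusted p = 6e-05, adjusted p = 0.32 with an estimated correlation), with Mcm5 at 905.8 ± 85.4 against 312.2 ± 34.1. Leukocyte markers rose in 14 of 19 cases and fell in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 2.6e-05, adjusted p = 0.31 with an estimated correlation), with Ptprc, which encodes CD45, at 1879 ± 94.9 against 338.1 ± 102.0. Of 12 fibroblast genes 9 rose (9 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.49 with an estimated correlation), with Col1a1 3.09-fold higher, and of 10 endothelial genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.008, adjusted p = 0.48 with an estimated correlation). Muscle transcripts fell: 17 of 20 striated muscle genes were lower and 2 higher (17 and 2 adjusted over the list alone, camera adjusted p = 3e-07, adjusted p = 0.32 with an estimated correlation), with Ckm at 8534 ± 955 against 33760 ± 3790 (-1.98, SE 0.14, adjusted p = 2.7e-08). Smooth muscle genes fell in 9 of 10 cases (10 adjusted over the list alone, camera adjusted p = 0.0021, adjusted p = 0.47 with an estimated correlation), with Lmod1 at 220.5 ± 105.0 against 1261 ± 128. Uox, which encodes urate oxidase, was present at 3180 ± 332 against 0.950 ± 0.855, and Slc26a4, which encodes the anion exchanger pendrin, at 620.0 ± 143.0 against 0.337 ± 0.390. Nfe2l2 fell to 4302 ± 96.2 from 5662 ± 371 (-0.39, SE 0.12, adjusted p = 0.011).

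With the striated muscle mean as a covariate, the count was 2387, and 4 calls ended, with smaller folds and standard errors about doubled. Nfe2l2 went from -0.39 (SE 0.12) to -0.25 (SE 0.27, adjusted p = 0.58), S100a8 from 9.16 (SE 1.05) to 6.76 (SE 2.36, adjusted p = 0.084), Ptprc from 2.51 (SE 0.26) to 1.65 (SE 0.54, adjusted p = 0.062) and Lmod1 from -2.61 (SE 0.26) to -1.63 (SE 0.53, adjusted p = 0.058). The muscle mean was 12.1 to 12.584 in KEAP1-deficient and 13.245 to 13.482 in wild-type libraries, so it moves with genotype.

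**Figure D3:**
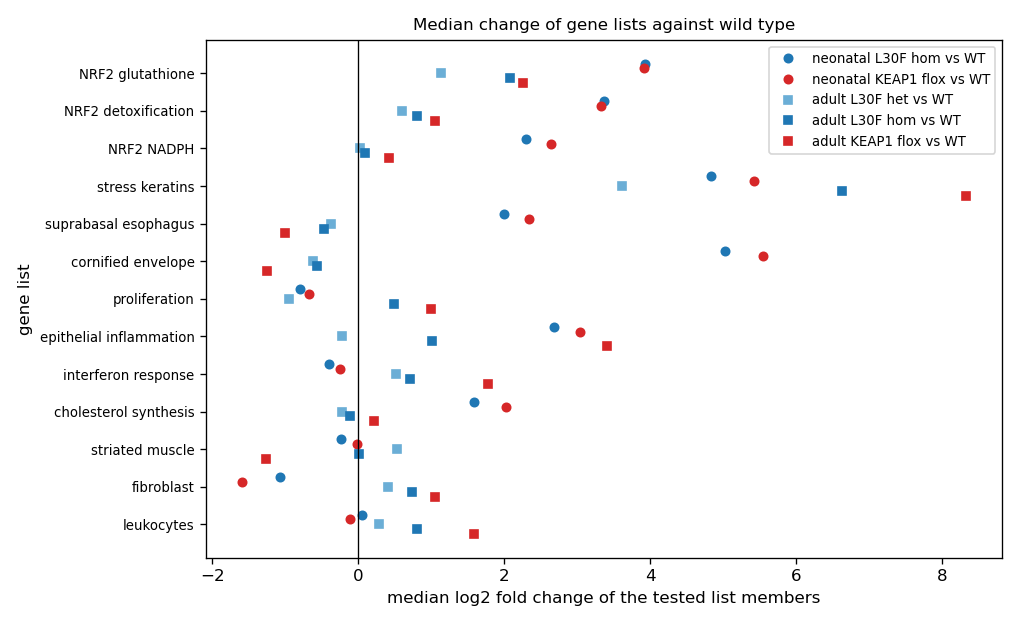
Median log2 fold change of the tested members of 13 gene lists (horizontal axis) in the 5 comparisons with wild type; circles are pups, squares adults, and colours genotypes, with near copies among the cornified envelope genes. The cornified envelope median was 5.02 and 5.54 in L30F homozygous and KEAP1-deficient pups and -0.57 and -1.25 in the adults.

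Homozygotes were compared with heterozygotes to ask how adult responses scale with L30F dose. With both alleles mutated, most genes of the glutathione, stress keratin and cell cycle lists were higher and Nfe2l2 was lower. Cell cycle calls were not graded with dose: against wild type most genes of the list fell in heterozygotes, while more rose than fell in homozygotes. Depths of homozygotes, heterozygotes and wild type did not overlap (10.9 to 11.6, 12.8 to 16.9 and 27.5 to 32.3 M reads). Dose therefore cannot be told apart from a batch. Striated muscle genes, described below, rose in heterozygotes against wild type, with few called in homozygotes. Slc7a11 had 31940 ± 4290 against 17190 ± 1910 (SD, n = 4; log2 fold change 0.89, SE 0.12, adjusted p = 0.00024) and Gclm 4854 ± 682 against 2525 ± 195 (0.94, SE 0.10, adjusted p = 3.1e-05). Krt6b was 12.4-fold and Krt16 7.16-fold higher, and Nfe2l2 fell by 1.31 on the log2 scale (SE 0.12, adjusted p = 1.1e-05). The test called 3249 genes, 1602 higher and 1647 lower.

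Among 13 glutathione genes 10 were higher (10 adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.28 with an estimated correlation). Of 35 detoxification genes 17 were higher and 2 lower (19 and 3 adjusted over the list alone, camera adjusted p = 2.9e-05, adjusted p = 0.40 with an estimated correlation), Akr1c18 13.2-fold. Of 4 stress keratins 3 were higher (3 adjusted over the list alone, camera adjusted p = 8.4e-05, adjusted p = 0.27 with an estimated correlation), and Krt14 was 2.93-fold higher. Of 20 cell cycle genes 17 were higher (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.9e-11, adjusted p = 0.27 with an estimated correlation), with Top2a at 2031 ± 334 against 749.3 ± 183.0 (log2 fold change 1.46, SE 0.23, adjusted p = 0.00093) and the mitotic kinase Bub1 3.18-fold higher. Striated muscle genes were lower in 10 of 20 cases and higher in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.40 with an estimated correlation), with Ckm at 25400 ± 3840 against 48020 ± 10000. Red blood cell genes were lower in 3 of 7 cases (7 adjusted over the list alone; median -3.68, camera adjusted p = 0.00034, adjusted p = 0.40 with an estimated correlation). Nqo1 was higher, 6304 ± 1430 against 4202 ± 406 (0.56, SE 0.13, adjusted p = 0.0078), but was not called with the muscle covariate (0.53, SE 0.17, adjusted p = 0.084) or with Ddx3y as a covariate (0.48, SE 0.15, adjusted p = 0.078), where the fold was slightly smaller and the standard error larger. The count was 844 with the muscle covariate, 1200 with Ddx3y as a covariate, 1544 in a fit of only these groups and 2132 without homozygote library 1.

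L30F homozygous adults were compared with KEAP1-deficient adults to ask how the mutation differs from KEAP1 loss at this age. Krt4 and Krt15 were higher, and most alarmin and interferon-stimulated genes of the lists lower, in homozygotes. Krt4 had 168800 ± 49100 in homozygotes against 9559 ± 6120 (SD, n = 4; log2 fold change 4.37, SE 0.40, adjusted p = 3.4e-06) and Krt15 5562 ± 1320 against 317.6 ± 174.0 (4.23, SE 0.25, adjusted p = 1.1e-07). Krt17 had 976.2 ± 427.0 against 30590 ± 4570 (-5.13, SE 1.15, adjusted p = 0.0054), and Il1b 37.8 ± 9.92 against 1277 ± 742 (-4.85, SE 0.60, adjusted p = 4.1e-05). Nqo1 had 6304 ± 1430 against 5950 ± 359 (0.06, SE 0.13, adjusted p = 0.78). The test called 5248 genes, 2568 higher and 2680 lower. Depth separated these groups completely, 10.9 to 11.6 M reads against 22.5 to 31.3 M, so a batch cannot be told apart from genotype.

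Of 13 glutathione genes 4 were lower in homozygotes (4 adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.66 with an estimated correlation), among them Gsr, glutathione reductase, at 1683 ± 391 against 3307 ± 397. Among 35 detoxification genes 8 were higher and 6 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.53): Aldh3a1 was 3.03-fold higher and Akr1b8 lower (log2 fold change -1.74, SE 0.21, adjusted p = 2.4e-05). Nfe2l2 was lower (-1.58, SE 0.12, adjusted p = 3.1e-07) and Keap1 higher (0.74, SE 0.07, adjusted p = 4.7e-06). Among 16 suprabasal genes 7 were higher and 3 lower (10 and 3 adjusted over the list alone, camera adjusted p = 0.0085, adjusted p = 0.66 with an estimated correlation), with Krt13 3.23-fold higher. Of 37 cornified envelope genes 13 were higher and 11 lower (16 and 11 adjusted over the list alone, camera adjusted p = 0.34; median 0.43, mean -0.12, of opposite sign, test direction up). Tgm6 was listed at 0 in all 4 homozygous libraries against 301.8 ± 121.0.

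Of 21 alarmin and cytokine genes 15 were lower (16 adjusted over the list alone, camera adjusted p = 7.2e-08, adjusted p = 0.13 with an estimated correlation). Of 16 interferon-stimulated genes 14 were lower (14 adjusted over the list alone, camera adjusted p = 6.3e-08, adjusted p = 0.39 with an estimated correlation), with Irf7 at 162.4 ± 35.1 against 574.8 ± 161.0. Leukocyte markers were lower in 12 of 19 cases and higher in 1 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00044, adjusted p = 0.66 with an estimated correlation); Cxcr2, a neutrophil chemokine receptor, had 150.8 ± 32.2 against 727.0 ± 219.0. Of 20 striated muscle genes 17 were higher and 1 lower (18 and 1 adjusted over the list alone, camera adjusted p = 1.4e-13, adjusted p = 0.33 with an estimated correlation), with Ckm 2.96-fold higher. With the muscle mean as a covariate the count was 67 and 15 of 21 gene results were no longer called. Krt4 (4.79, SE 1.05, adjusted p = 0.084), Krt13 (1.72, SE 0.36, adjusted p = 0.055) and Krt17 (-9.01, SE 2.78, adjusted p = 0.2) had folds at least as large as without it, but larger standard errors ended their calls. For others the fold shrank too: Il1b went from -4.85 (SE 0.60) to -3.64 (SE 1.54, adjusted p = 0.34), Irf7 from -1.79 (SE 0.25) to -1.48 (SE 0.65, adjusted p = 0.35) and Oasl2 from -1.21 (SE 0.16) to -0.63 (SE 0.39, adjusted p = 0.53). Ptprc went from -1.44 (SE 0.26) to -0.45 (SE 0.60, adjusted p = 0.8). Ckm went from 1.57 (SE 0.14) to 0.81 (SE 0.30, adjusted p = 0.27), but it is part of the muscle mean and was adjusted in part for itself. Nfe2l2 (-1.75, adjusted p = 0.027), Krt15 (4.88, adjusted p = 0.011), Akr1b8 (-2.62, adjusted p = 0.035), Slc26a4 (-7.81, adjusted p = 0.025) and Tgm6 stayed called. The muscle mean was 13.372 to 13.873 in homozygotes and 12.1 to 12.584 in KEAP1-deficient libraries, without overlap.

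Against wild type, 3614 genes were called in the same direction in adult homozygotes and KEAP1-deficient adults, 2015 higher and 1599 lower, and 36 in opposite directions. Independent lists would share 565 and 470, and 50 simulations of unchanged groups shared 0 and 0, where almost no gene is called. Across genes, which are not independent replicates, the covariance of fold changes was 0.538 (simulated 0.063). With the controls split between the comparisons in 6 ways, 932 to 1270 higher and 611 to 903 lower genes were shared and the covariance was 0.461 to 0.499.

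L30F heterozygous adults were compared with KEAP1-deficient adults, the adult groups with the fewest and the most genes called against wild type. Gsr, Slc7a11 and Nqo1 were lower in heterozygotes, with log2 fold changes of -1.95 (SE 0.15, n = 4, adjusted p = 5.7e-08), -1.43 (SE 0.12, adjusted p = 1.4e-07) and -0.50 (SE 0.13, adjusted p = 0.0041). Krt4 was 43.4-fold and Krt15 35.3-fold higher, and Krt16 had 3351 ± 2390 against 90860 ± 6860. Il1b had 6.71 ± 3.53 against 1277 ± 742 (-7.26, SE 0.60, adjusted p = 2.3e-07). The test called 8891 genes, 4290 higher and 4601 lower. Here too depth separated the groups, 12.8 to 16.9 M reads against 22.5 to 31.3 M, so batch and genotype cannot be told apart.

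Among 13 glutathione genes 11 were lower in heterozygotes (11 adjusted over the list alone, camera adjusted p = 7.7e-06, adjusted p = 0.39 with an estimated correlation). All 4 stress keratins were lower (4 adjusted over the list alone, camera adjusted p = 0.00062, adjusted p = 0.29 with an estimated correlation). Of 16 suprabasal genes 10 were higher and 3 lower (10 and 3 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.58 with an estimated correlation). Of 20 cell cycle genes 19 were lower (19 adjusted over the list alone, camera adjusted p = 7.8e-09, adjusted p = 0.29 with an estimated correlation), with Cdk1 at 89.9 ± 25.4 against 361.8 ± 30.3 (log2 fold change -2.03, SE 0.25, adjusted p = 9.5e-06). Of 21 alarmin and cytokine genes 17 were lower (18 adjusted over the list alone, camera adjusted p = 1.6e-07, adjusted p = 0.15 with an estimated correlation). Of 16 interferon-stimulated genes 15 were lower (15 adjusted over the list alone, camera adjusted p = 7.7e-06, adjusted p = 0.40 with an estimated correlation), Oasl2 among them (-1.83, SE 0.16, adjusted p = 3.1e-07). Leukocyte markers were lower in 13 of 19 cases and higher in 2 (14 and 2 adjusted over the list alone, camera adjusted p = 0.00027, adjusted p = 0.43 with an estimated correlation). Striated muscle genes were higher in 17 of 20 and lower in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 2e-10, adjusted p = 0.29 with an estimated correlation). Nfe2l2 had 3565 ± 385 against 4302 ± 96.2 (-0.28, SE 0.12, adjusted p = 0.063). It was called by limma-voom (adjusted p = 0.048), with a replicate block (0.045), in a fit of only these groups (0.021), without heterozygote library 1 (-0.35, adjusted p = 0.026) and without homozygote library 1, 3 or 4 (adjusted p = 0.03, 0.046 and 0.045). With the muscle mean as a covariate the count was 71 and 14 of 17 gene results were no longer called, Krt4 (6.00, SE 1.36, adjusted p = 0.078), Krt16 (-6.29, SE 1.34, adjusted p = 0.068) and Il1b (-5.64, SE 1.99, adjusted p = 0.21) among them. Their standard errors without it were 0.40, 0.41 and 0.60. Ckm, which is part of the muscle mean itself, is also among the 14. The calls of Gsr (-2.24, SE 0.49, adjusted p = 0.064) and Nqo1 (-0.37, SE 0.43, adjusted p = 0.73) ended as well, and that of Nqo1 also ended with Ddx3y as a covariate (-0.39, SE 0.17, adjusted p = 0.083). The muscle covariate took Cdk1 from -2.03 (SE 0.25) to -1.26 (SE 0.83, adjusted p = 0.51) and Oasl2 from -1.83 (SE 0.16) to -1.05 (SE 0.51, adjusted p = 0.35). Krt15 (6.01, adjusted p = 0.011) and Slc7a11 (-2.06, adjusted p = 0.028) stayed called.

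The effects of the same genotype against its own wild type were compared between pups and adults for 19031 genes, which differ in age, Cre driver and tamoxifen together. The effect of L30F homozygosity differed for 6369 genes and that of KEAP1 loss for 8967. The NRF2 targets Slc7a11 and Nqo1 had smaller effects in adults: the log2 effect on Slc7a11 differed by -5.57 (SE 0.14, adjusted p = 2e-19) for L30F and -5.30 (SE 0.14, adjusted p = 6.4e-19) for KEAP1 loss, and that on Nqo1 by -4.50 (SE 0.15, adjusted p = 6.9e-17) and -4.83 (SE 0.15, adjusted p = 9.2e-18). Wild-type Slc7a11 and Nqo1 were at 57.7 ± 1.49 and 76.7 ± 4.42 in pups and 1210 ± 163 and 1088 ± 111 in adults, in tables normalized separately. The effect on the cell cycle gene Mcm2 differed by 1.89 (SE 0.20, adjusted p = 3.7e-08) for L30F, which lowered it in pups and raised it in adults. Of 2353 genes called for L30F at both ages, 993 rose in both, 420 fell in both and 940 went opposite ways; independent lists would give 544, 347 and 872. Of 5280 genes called for KEAP1 loss at both ages, 1898 rose in both, 1265 fell in both and 2117 went opposite ways; independent lists would give 1287, 1009 and 2288.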

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

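The comparison of effects between pups and adults, and the tests below on the Nfe2l2 change in pups and against KEAP1 loss, on glutathione genes, on genes shared with KEAP1 loss, on the depth ranges and on muscle and fibroblast markers, were chosen after the results were seen.

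A library lay far from the other 3 of its group for 13 of 177 groups of values tested, by Dixon's test at a level of about 1 in 20. The groups share libraries and mostly hold genes chosen after their values were seen, so this count was not compared with chance. Wild-type adult library 4 had Krt16 at 215.7 (others 79.3 to 101.4), Krt6a at 4444.8 (1257.8 to 1512.6), Top2a at 871.1 (1798.6 to 1961.0) and Mcm2 at 410.0 (285.9 to 300.3). Other wild-type adults stood apart for Prdx1 (3145.3 in library 2, others 3272.6 to 3287.2) and Il1b (52.9 in library 3, others 5.4 to 13.3). Among heterozygotes, library 1 had Krt16 at 6919.6 (1907.2 to 2394.3) and library 2 Cxcl5 at 7.2 (0 to 1.2). Among homozygotes, library 3 had Pecam1 at 1848.0 (1517.2 to 1534.9), and library 4 had Krt17 at 338.2 (1139.2 to 1229.0) and Cxcl3 at 3.5 (0 in the others). KEAP1-deficient adult library 1 had Lmod1 at 378.6 (161.3 to 172.5) and Gsr at 3895.8 (3023.1 to 3170.9).

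Effects differed between adults and pups for 6369 genes under L30F homozygosity and 8967 under KEAP1 loss. For L30F the adult effect minus the pup effect (log2) was -2.29 for Nfe2l2, -4.50 for Nqo1, -5.57 for Slc7a11, -1.72 for Gclc, 1.25 for Krt6b, -1.79 for Il1a and 1.89 for Mcm2, with adjusted p from 2e-19 to 0.022. For KEAP1 loss it was -1.33 for Nfe2l2, -4.83 for Nqo1, -5.30 for Slc7a11, -1.71 for Gclc, 1.08 for Krt6b and 2.10 for Krt16, with adjusted p from 6.4e-19 to 0.034. Age, Cre driver and tamoxifen differ together, and their parts were not tested.

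Nfe2l2 reads were lower in adult L30F groups. Lower depth of those libraries is argued against by a log2 change of -1.97 in homozygotes after thinning to equal depth. Reduced counting of the mutant allele in any tissue, by as much as in adults, is argued against by 0.31 (SE 0.17) in homozygous pups. A smaller reduction is not excluded, because Nfe2l2 rose by 0.93 in KEAP1-deficient pups and such a rise could offset it. For loss of differentiated epithelium, Nfe2l2 was lower in homozygotes than in KEAP1-deficient adults (-1.58, SE 0.12), although Krt4 was higher in homozygotes. This does not decide the question, because a rise of Nfe2l2 with KEAP1 loss, as in pups, could mask a fall. Depth also separates those groups. A response of Nfe2l2 to the mutation in adults is a hypothesis that was not tested. Age, Cre driver, tamoxifen, loss of differentiated epithelium and a batch of the shallow L30F libraries stay open. Reduced counting of the mutant allele that is confined to adults stays open too.

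Adult homozygotes and wild type differed in 4420 genes in libraries of unequal depth. Depth alone is argued against by 3859 genes called at equal depth. No label names a batch. For the genes also called with KEAP1 loss, as a set, a batch of the shallow L30F libraries alone is argued against. With other wild-type libraries as controls for each mutant, at least 1543 genes went the same way in each of 6 splits (independent lists, 357 to 528). At most 39 went opposite ways (352 to 526). Of the KEAP1-deficient libraries, only library 1 (31.3 M reads) lies within the depths of wild type. The others (22.5, 23.1 and 25 M) lie below them. A batch that set both mutants apart from wild type would also give such calls, so the splits do not argue against it. For the glutathione list, 10 members were higher in homozygotes than in heterozygotes, but this does not exclude a batch, because depth separates those groups too (10.9 to 11.6 M reads against 12.8 to 16.9 M). For all other genes a batch cannot be told apart from genotype: the deepest L30F library has 16.9 M reads and the shallowest wild-type library 27.5 M. Between the L30F groups and KEAP1-deficient adults, whose shallowest library has 22.5 M reads, batch and genotype cannot be told apart either.

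Striated muscle markers were lower in KEAP1-deficient adults. A larger share of epithelium lowering all other cell types alike is argued against by the fibroblast median of 1.05. Less muscle coat in the sample may explain the fall, since the smooth muscle median was -0.88, with 9 of 10 members lower; a fall inside muscle cells would look alike.

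Other splits of the libraries were tested for each count. With 10 splits of pup libraries the splits are too few to argue against chance for genes. The real split called 8225, 10404 and 875 genes (L30F and KEAP1 loss against wild type, and against each other) and the highest other 1, 1 and 2. The lists were 16, 17 and 17, with highest others of 20, 19 and 19. Of the 10 splits 4, 3 and 3, the real split included, reached the real list count, so chance cannot be excluded for pup lists. In adults chance is argued against for genes but not excluded. Only 1 of 35 splits, the real split, reached the count, the lowest share that 35 splits can give, without adjustment over comparisons. Against wild type the counts were 1927 in heterozygotes (highest other 586), 4420 in homozygotes (51) and 9290 with KEAP1 loss (1). They were 3249 for homozygotes against heterozygotes (219), 5248 for homozygotes against KEAP1 loss (3) and 8891 for heterozygotes against KEAP1 loss (3). The split with 586 genes exchanges wild-type library 4 and heterozygote library 4. For adult lists chance cannot be excluded either: in the same order 14 (highest other 15), 13 (13), 12 (18), 9 (12), 12 (13) and 12 (14), reached by 6, 3, 15, 12, 4 and 9 of 35 splits.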

How the results depend on the processing

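Effect differences between ages, thinning and the offset of 4 were chosen after seeing the data. A count test planned only for deposited counts was not run, although recovered reads would allow it (limma-voom was run on them), and neither was the planned joint interaction. Comparisons are ordered here as pups L30F and KEAP1 loss against wild type, then against each other; adults heterozygotes, homozygotes and KEAP1 loss against wild type, then homozygotes against heterozygotes, homozygotes and heterozygotes against KEAP1 loss.

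A 2-fold threshold gave 3295, 4676, 148, 457, 1167, 3515, 907, 1713 and 3485 genes, overlaps of 2833 and 906, and effect differences of 3131 (L30F) and 4986 (KEAP1 loss), because it adds a condition. An estimated correlation left 2, 2, 0, 0, 0, 0, 0, 0 and 0 lists. Fry called 11 lists between the pup mutants, 21 in adult KEAP1 loss against wild type and 20 in heterozygotes against KEAP1 loss. The labels do not say whether equal replicate numbers pair libraries. Deviations of equally numbered libraries correlated at -0.104 to 0.219 in pups and -0.074 to 0.095 in adults, which gives no clear sign of pairing but does not exclude it. The value of 0.219, wild-type library 3 with KEAP1-deficient library 3, was the largest between pup libraries of different groups. A replicate block gave 222 genes between the pup mutants.

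A fit of only the groups compared gave 185 genes between the pup mutants, 809 for heterozygotes against wild type and 1544 for homozygotes against heterozygotes, with fewer libraries to estimate the spread. The striated muscle covariate, which moves with genotype in adults, gave 113, 2387, 844, 67 and 71 genes (heterozygotes and KEAP1 loss against wild type, homozygotes against heterozygotes, then homozygotes and heterozygotes against KEAP1 loss), and 3 and 7 lists in the last comparisons named. With Ddx3y as a covariate 653 genes were called for heterozygotes against wild type and 1200 for homozygotes against heterozygotes. On the deposited log2 scale Ddx3y was 10.15 to 10.44 in heterozygotes. It was lower, without overlap, in wild type (10 to 10.1) and KEAP1-deficient adults (9.83 to 10.09), so the covariate moves with genotype there. Homozygotes (9.76 to 10.32) overlapped heterozygotes, and the cause of the lower count in that comparison was not tested.

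Leaving out each library gave 6507 to 8307, 8780 to 10588, 47 to 924, 623 to 2448, 3057 to 4984, 8246 to 9669, 2132 to 3314, 4097 to 5699 and 8019 to 9088 genes. It gave overlaps of 5840 to 7118 and 2566 to 4060, and effect differences of 5454 to 6597 (L30F) and 8164 to 9177 (KEAP1 loss). Lists were 16 to 18, 17 to 20, 14 to 18, 12 to 17, 12 to 15, 12 to 13, 9 to 11, 11 to 13 and 10 to 15. Counts moved over 1.5 times between the pup mutants without wild-type library 2 (120) or 3 (207), homozygote 1 (172) or 2 (63), or KEAP1-deficient library 1 (177), 2 (47) or 3 (392). They did so in adult heterozygotes against wild type without wild-type library 1 (623), 2 (1151) or 3 (968), and in homozygotes against heterozygotes without homozygote 1 (2132); the cause was not tested.

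Over 5019 alternatives of 196 gene results, 4872 kept direction and side of the threshold, 137 were no longer called, 10 became called and 0 reversed; 120 results held under every setting. The muscle covariate ended 47 calls, the 2-fold threshold 34, leaving out a library 35 and Ddx3y 10. Those 47 include calls of Ckm, Myh1 and Myoz1, which are part of the muscle mean. All 196 held under TMM scaling, no filter, offsets of 0.1, 4 and 5, and thinning.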

Other observations

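Metabolic and stress genes beyond those above moved in pups. Of 15 glycolysis genes 11 rose and 1 fell in L30F homozygotes (11 and 1 adjusted over the list alone, camera adjusted p = 5.5e-05, adjusted p = 0.13 with an estimated correlation) and 11 rose with KEAP1 loss (11 adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.14 with an estimated correlation). Of 10 fatty acid synthesis genes 7 rose in homozygotes (7 adjusted over the list alone, camera adjusted p = 0.0003, adjusted p = 0.15 with an estimated correlation), and 7 rose and 1 fell with KEAP1 loss (7 and 1 adjusted over the list alone, camera adjusted p = 0.00083, adjusted p = 0.19 with an estimated correlation). Of 16 ATF4 and unfolded protein response genes 9 rose in homozygotes (10 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.13 with an estimated correlation) and 12 with KEAP1 loss (12 adjusted over the list alone, camera adjusted p = 0.00012, adjusted p = 0.12 with an estimated correlation). Of 12 immediate early genes 10 rose in homozygotes (11 adjusted over the list alone, camera adjusted p = 4.1e-05, adjusted p = 0.11 with an estimated correlation) and 10 with KEAP1 loss (10 adjusted over the list alone, camera adjusted p = 0.00057, adjusted p = 0.17 with an estimated correlation). In adults camera called none of these 4 lists against wild type: in heterozygotes, homozygotes and KEAP1 loss, adjusted p was 0.18, 0.26 and 0.24 for glycolysis, 0.16, 0.12 and 0.78 for fatty acids, 0.39, 0.56 and 0.15 for ATF4, and 0.11, 0.57 and 0.25 for immediate early genes. Members still rose with KEAP1 loss in adults: 7 of 15 glycolysis genes, with 2 lower (7 and 2 adjusted over the list alone, fry adjusted p = 0.032), 7 of 16 ATF4 genes, with 3 lower (7 and 3 adjusted over the list alone, fry adjusted p = 0.0046), and 5 of 12 immediate early genes, with 1 lower (5 and 2 adjusted over the list alone, fry adjusted p = 0.032); fry called these 3 lists up.

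Of 15 p53 target genes 9 rose and 1 fell in homozygous pups (9 and 1 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.11 with an estimated correlation). In KEAP1-deficient pups 9 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.16 with an estimated correlation), and in adult homozygotes 8 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.057 with an estimated correlation). In adult heterozygotes 3 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.17 with an estimated correlation), and with KEAP1 loss 6 rose and 3 fell (6 and 3 adjusted over the list alone) without a call by camera (adjusted p = 0.13), while fry called the list up (adjusted p = 1.4e-06). Of 13 Notch genes 1 was higher and 2 lower in adult heterozygotes (1 and 3 adjusted over the list alone, camera adjusted p = 0.033, adjusted p = 0.25 with an estimated correlation), 0 and 4 in homozygotes (0 and 4 adjusted over the list alone, camera adjusted p = 0.065) and 1 and 3 with KEAP1 loss (1 and 3 adjusted over the list alone, camera adjusted p = 0.40). Fry called the list down in these adults (adjusted p = 0.01, 0.0056 and 0.043). Camera did not call 5 aryl hydrocarbon receptor targets against wild type in pups (camera adjusted p = 0.14 and 0.42) or adults (0.19, 0.57 and 0.19), but fry called them up in pups (adjusted p = 4.3e-08 and 4.7e-08) and adults (0.00076, 0.00014 and 3.4e-07). The list shares a member with another list tested here, so a separate response of these targets is not shown. Of these 5, 3 rose and 1 fell in homozygous pups (3 and 1 adjusted over the list alone) and in KEAP1-deficient adults (3 and 1 adjusted over the list alone). In KEAP1-deficient pups 2 rose and 2 fell (2 and 2 adjusted over the list alone).

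Markers of neighbouring tissues stood out in single pup libraries. The mean log2 value of glandular stomach genes was 8.909 in KEAP1-deficient library 2 against 0.938 to 3.569 in the other pups, and that of thyroid and airway genes 6.837 in homozygote library 1 against 1.747 to 4.06. Camera called neither list against wild type: adjusted p for glandular stomach was 0.73 and 0.79 in pups and 0.19, 0.89 and 0.80 in adults, and for thyroid and airway 0.57 and 0.17 in pups and 0.63, 0.25 and 0.37 in adults. Fry called thyroid and airway genes lower in adult homozygotes (adjusted p = 0.013) and KEAP1 loss (adjusted p = 0.0056), and glandular stomach genes lower in heterozygotes (adjusted p = 0.04). Adipose genes were called in adult homozygotes, 1 of 8 lower (3 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.59 with an estimated correlation). Red blood cell genes were called there too, 1 of 7 lower (7 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.49 with an estimated correlation).

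The third L30F homozygous pup differed from the other 8 pups in sex-linked genes, with Xist at 15.53 and Ddx3y at 2 on the deposited log2 scale, where 2 is 0 reads; the others had Xist at 4.63 to 6.34 and Ddx3y at 9.09 to 10.33. In adults Ddx3y was 9.76 to 10.44 in all 16 libraries.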
